A study of Drosophila melanogaster with 2 samples.

How the data were processed

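Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 16 hours, with males and females pooled. The embryos came from a transgenic line that stably carries Usf fused at its C terminus to green fluorescent protein (GFP), and the fusion protein was pulled down with an antibody against GFP. Usf is the fly member of the upstream stimulatory factor family, basic helix-loop-helix leucine zipper transcription factors whose vertebrate members bind the E-box CACGTG. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. There were 2 samples in 1 group, biological replicates 3 and 4 by the numbers the labels give them. No control library was among the samples analysed here, and both replicates were called against the same control alignment, per the deposited sample notes.

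The deposited files were peak lists in narrowPeak layout, on the genome builds dm3 and dm6. For each build there was a relaxed list for replicate 3, a relaxed list for replicate 4, a relaxed list called on the pooled reads of both replicates, and an optimal list thresholded by the irreproducible discovery rate (IDR), which keeps peaks whose ranks recur between replicates. The relaxed lists hold peaks together with background and were the input of the IDR step, per the deposited sample notes. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each peak carried a signal value and a summit position made by the authors. The scaling of that signal is not stated, so the deposited signal was used only to rank and describe peaks within a list. Every IDR peak carried the same signal as the identical peak in the pooled list, and the 2767 IDR peaks on dm6 were the 2767 strongest of the 21315 pooled peaks. Read depth is unknown, and intervals given for shares are 95% Wilson intervals that cover counting error over peaks or genes.

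Peaks on dm6 were joined to the Release 6 genome sequence and to the Ensembl 115 annotation (FlyBase 6.54), which share that coordinate system. All dm6 peak ends lay within the chromosome lengths of that sequence. As a check of the sequence and annotation, 30565 of 30788 annotated start codon features (99.3%) read ATG. The dm3 lists were analysed only by position within dm3, with no gene annotation and no conversion of coordinates. Coordinates are given counting from 1. Genes and transcripts on the chromosome arms were used, apart from transposable elements. That left 18277 genes, of which 13968 were protein-coding. Of the symbols written in the gene lists, only Tor was left without a gene in the annotation. Of 185 chemoreceptor genes, the 179 annotated as protein-coding were tested.

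Peaks were matched between lists when their summits lay within 100 bp. Overlap was tested against 1000 random draws of as many peaks from the other replicate's relaxed list, and distance to a transcription start site (TSS) against 1000 random placements on the same chromosome arm. The signal correlation and the trend of CACGTG with signal had permutation tests with 100000 resamples. The motif CACGTG was searched in 201 bp centred on the summit and in control windows of the same length 500 bp to each side. The share at summits was compared with 1 control window per peak, on a side drawn at random, by an exact McNemar test. All hexamers, with reverse complements merged, were counted in 101 bp at the summit and in the control windows, and tested by exact binomial tests with Benjamini-Hochberg adjustment. These binomial tests take the share in the control windows as fixed, so their p-values leave out its counting error. A gene was said to have a peak when an IDR summit lay within 1 kb of one of its TSSs. Each of 25 gene lists was compared with the remaining protein-coding genes (all genes for the tRNA list) by Fisher's exact test, adjusted over the 25 lists. Peak density on the X chromosome was compared with the 4 long autosome arms by an exact binomial test. Tests were two-sided, except those of replicate overlap on random draws and of TSS distance on random placements. These 2 asked for a value as high as the observed one. Draws of windows matched for GC content were tested two-sided, and the threshold was 0.05. Peaks and genes are not independent replicates of an embryo collection, so these p-values describe the peak lists of 2 samples.

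The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Usf, the first 25 protein-coding genes by falling IDR signal whose peak lay within 1 kb of a TSS and was matched in both replicates, the 4 strongest members of each list that passed its test, and any member of the E-box factor, clock and V-ATPase lists. It also names the 3 strongest peaks specific to each replicate, and asks for the sequence at the strongest of those 25 genes whose peak holds CACGTG. Genes that share a peak with a named gene, the pair Mybbp1A and RpL36, and the hexamers and octamers given by sequence, were chosen after their values were seen. Only 2 of the 25 genes had CACGTG, where the rule allowed 5. The alternatives were other summit and TSS distances, other window lengths, other control windows, stricter and looser sets of peaks, other gene backgrounds, the dm3 lists and the lists of single replicates in place of the pooled list. Comparisons chosen after seeing the data included control windows matched for GC content, the GC profile, octamers and comparisons between pairs of gene lists. Divergent promoters, the X density of relaxed peaks, dm3 counts off the arms and the ribosome biogenesis list without Rrp1 were also chosen then. So were tests on the strongest 276 peaks, pooled lists of other complexes and the 500 bp distance for replicate-specific peaks. Matched windows were drawn from 577662 random positions over 1000 bp from any IDR summit. Each had the same GC count as the peak's window or the nearest count with at least 5 candidates, the same state of lying within 1 kb of a TSS, and the same state of lying in coding sequence. A further set was matched for distance to a TSS in classes of up to 100, 300 and 1000 bp and beyond.

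The shared functions were tested on simulated data before use. Of 10 hexamers planted in 2767 simulated windows, 10 were recovered, and 1 hexamer was called with none planted. Simulated summit and control windows had equal base composition. In the data GC content was 33.7% at summits and 44.2% in control windows, so that number of false calls does not carry over. Of 25 simulated gene lists, the 5 planted ones were recovered, with 0 false calls among the other lists. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.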

Results

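Binding of Usf-GFP was profiled by ChIP-seq in 2 biological replicates of whole embryos aged 0 to 16 hours, numbered 3 and 4. The lists on dm6 held 28459 relaxed peaks for replicate 3, 29246 for replicate 4, 21315 for the pooled reads and 2767 in the IDR set. The median peak spanned 396 bp in the IDR set. The authors' signal of the IDR peaks ran from 71.3 to 1798, with a median of 118.9. Read depth was unknown.

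The strongest Usf-GFP peaks near protein-coding genes mostly had a TSS of another coding gene within 1 kb too, and 2 of the first 25 held the E-box CACGTG. The highest peak of all, with a signal of 1798, lay on 3L at 19590414–19590817, 108 bp upstream of a TSS of CG14100, and ranked 1 in both replicates. The second lay on X at 2703689–2704081, 41 bp upstream of Ugalt, which transports UDP-galactose into the Golgi, and within 1 kb of eIF2Bbeta, a translation initiation factor subunit. Its pooled signal was 1530, and it ranked 2 in replicate 3 and 3 in replicate 4. A peak with a signal of 1295 lay in sequence annotated as intron, 480 bp upstream of the nearest coding TSS, which belongs to the Polycomb group gene ph-p. Chro, which encodes the chromodomain protein Chromator, had a peak of 1234 whose summit was annotated as 5′ UTR, and which also lay within 1 kb of the transcription and repair factor gene Ssl1. The next genes in order were CG1888, px, CG14860, Tcs5, Art3, HmgZ and Adf1, with signals from 1081 down to 925.9. CG5611, Shc, Lk6, mRpL41, CG18428, Vha55, CG9147, PNPase, CenG1A, CG9663, CG8320, Pal1, PTPMT1 and CG5098 followed, with signals from 871.1 down to 783.6.

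Of these 25 genes, 18 had another protein-coding gene with a TSS within 1 kb of the same summit, and 18 had the summit within 200 bp of their own TSS. The first count took TSSs in any orientation and was not set against other peaks or random positions. The partners included the mitochondrial ribosomal protein genes mRpS10 beside Art3 and mRpS23 beside CenG1A, the endosomal sorting gene CHMP2B beside Tcs5, and the peroxisome gene Pex11ab beside CG8320. None of the 25 summits lay in a coding exon. All 25 peaks ranked at 39 or better in each replicate. The E-box CACGTG lay within 100 bp of the summit in 2 of the 25, at CG14860 and Vha55. Over all IDR peaks it did so in 68 of 2767 (2.46%), and the difference was not tested.

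At CG14860, the peak lay on 3R at 14894331–14894824 with its summit at 14894528, in intergenic sequence. A TSS of the diphthamide synthesis gene Dph2 lay within 1 kb of that summit. The peak's pooled signal was 1046, with 611.8 in replicate 3 (rank 6) and 436.6 in replicate 4 (rank 13). The hexamer occupied 14894490–14894495, also in intergenic sequence. The 36 bp around it, at 14894475–14894510, read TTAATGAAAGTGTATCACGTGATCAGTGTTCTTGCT. At Vha55, which encodes the B subunit of the vacuolar proton pump, the peak lay on 3R at 12627661–12628061 with its summit at 12627835, 6 bp upstream of a TSS and within 1 kb of the sorting nexin gene Snx3. Its signal was 802.3, with 458.2 in replicate 3 (rank 20) and 351.7 in replicate 4 (rank 28). CACGTG occupied 12627768–12627773, in sequence annotated as 5′ UTR, inside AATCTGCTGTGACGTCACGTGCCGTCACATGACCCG at 12627753–12627788.

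The Usf gene itself (X, 4544617–4548794, minus strand) had no IDR peak inside it or within 5 kb of its ends. The relaxed pooled list held 3 peaks in that range, with signals of 57.1, 27.3 and 27.0. The one inside the gene, with its summit at 4547215 in an intron, ranked 13024, and the highest of the 3 ranked 3636.

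The gene lists asked which processes had Usf-GFP peaks at their promoters. Genes of the vacuolar proton pump (V-ATPase), which acidifies lysosomes and endosomes, and genes of the cytosolic ribosome carried peaks far more often than other genes. An IDR summit lay within 1 kb of a TSS in 15 of 21 V-ATPase genes (71.4%, against 15.2% of other coding genes; Fisher's exact test, adjusted p = 9.0e-08). That list was written gene by gene and may leave out paralogs of the pump's subunits. Its strongest members were Vha55, Vha44 with a signal of 348.7, Vha26 with 298.1 and VhaM9.7-b with 276.9. Further members with a peak were VhaAC45, Vha14-1, Vha100-2, Vha16-1, Vha36-1, VhaPPA1-1, ATP6AP2, Vha68-1, VhaAC39-1, Vha13 and VhaSFD. Vha68-2, Vha100-1, Vha100-3, Vha100-4, Vha100-5 and VhaM9.7-a had none. Among cytosolic ribosomal protein genes, 60 of 86 had a peak (69.8% against 14.9%; Fisher's exact test, adjusted p = 1.5e-28). Their strongest members were RpL7 (signal 484.8), RpS27 (472.9), RpL34b (380.9) and RpL23A (367.0). CACGTG lay within 100 bp of the strongest peak's summit in 2 of the 15 V-ATPase genes, Vha55 and Vha44, and in 4 of the 60 ribosomal protein genes, RpL7 among them. With only the 68 IDR peaks that held CACGTG, V-ATPase did not pass (2 of 21, Fisher's exact test, adjusted p = 0.083). Cytosolic ribosomal proteins did (4 of 86, Fisher's exact test, adjusted p = 0.041). All coding genes remained the background, so this result carries the higher share of these genes with any IDR peak. Among genes with an IDR peak, 4 of 60 ribosomal protein genes and 78 of 2071 others had one with CACGTG, a difference that was not tested.

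A further 3 lists passed. Among lipid synthesis genes 7 of 15 had a peak (46.7%; Fisher's exact test, adjusted p = 0.016), led by Lpin, Gpat4, FASN1 and Zw with signals of 238.5, 202.6, 122.9 and 97.7. Among E-box-binding transcription factors and their partners 5 of 9 had one (55.6%; Fisher's exact test, adjusted p = 0.020): SREBP, a regulator of lipid synthesis genes, with 176.4, bigmax with 170.5, crp with 114.1, Mondo, a glucose-sensing factor, with 81.3, and Mnt with 77.5. Myc, Max, Mitf and Usf had none. Among ribosome biogenesis genes 10 of 28 had a peak (35.7%; Fisher's exact test, adjusted p = 0.020), with eIF6 at 746.1, Ns2 at 359.7, Rrp1 at 308.2 and nop5 at 134.8. Rrp1 encodes a DNA repair endonuclease and not a ribosome factor. Without it, a change made after seeing the data, the count was 9 of 27 (33.3%; Fisher's exact test, adjusted p = 0.048). None of the 5 E-box factor peaks and none of the 7 lipid synthesis peaks held CACGTG near the summit. Of the 10 ribosome biogenesis genes with a peak, 2 had it there. With only the IDR peaks that held CACGTG, ribosome biogenesis did not pass (2 of 28; Fisher's exact test, adjusted p = 0.097). With the background limited to genes with any relaxed peak, V-ATPase and cytosolic ribosomal proteins still passed and these 3 did not (Fisher's exact test, adjusted p = 0.073, 0.43 and 0.38). Nor did these 3 pass with the 1383 stronger IDR peaks (Fisher's exact test, adjusted p = 0.29, 0.34 and 0.26). The E-box factors also failed with replicate 4 alone (4 of 9; Fisher's exact test, adjusted p = 0.085) and at a TSS distance of 500 bp (3 of 9; 0.20). Neighbouring genes that share a peak, such as VhaM9.7-b and COX8, are not independent. Mybbp1A, counted among the 10 ribosome biogenesis genes, shares its peak with the cytosolic ribosomal protein gene RpL36. The ribosome biogenesis list was not tested without Mybbp1A.

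**Figure D1:**
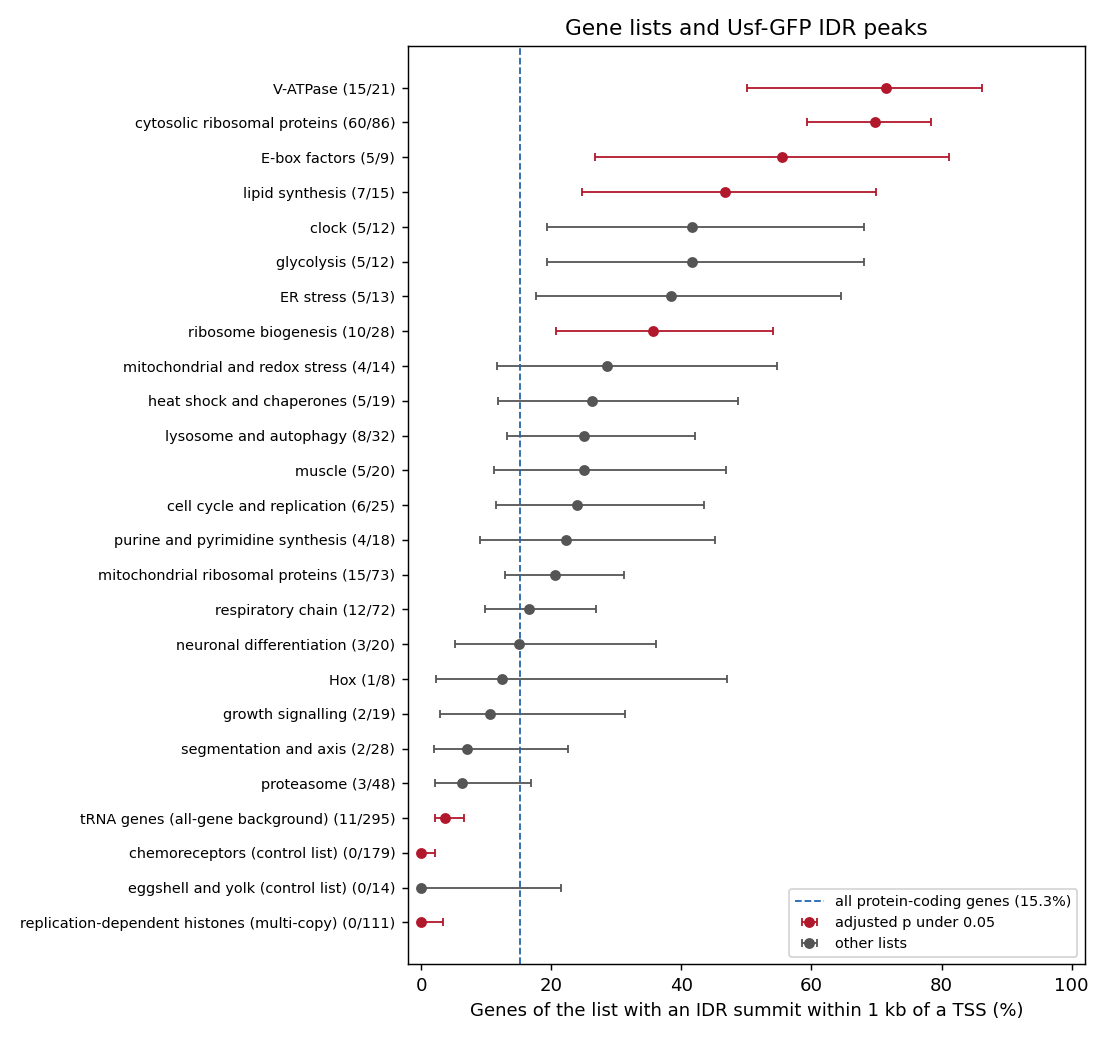
Share of the genes of each list (percent, with 95% Wilson intervals) that had an IDR summit within 1 kb of a TSS, in red where the adjusted p passed, with the counts of genes beside each name and the share of all protein-coding genes (15.3%) as a dashed line. V-ATPase (71.4%) and cytosolic ribosomal proteins (69.8%) stood highest, and chemoreceptors and histones had 0 genes with a peak.

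Lists of other large protein complexes did not pass. They took every gene whose symbol followed a pattern, unlike the V-ATPase list, so the lists were not built alike. Peaks lay at 15 of 73 mitochondrial ribosomal protein genes (20.5%), 12 of 72 respiratory chain genes (16.7%) and 3 of 48 proteasome genes (6.25%). In comparisons chosen after seeing the data, the share was higher for cytosolic than for mitochondrial ribosomal proteins (Fisher's exact test, adjusted p = 2.5e-09 over 4 such pairs). It was also higher for V-ATPase than for proteasome genes (Fisher's exact test, adjusted p = 1.1e-07), respiratory chain genes (6.1e-06) and other lysosome and autophagy genes (8 of 32, 25.0%; 0.0016). The lysosome and autophagy list itself passed only at 2000 bp from a TSS (12 of 32; Fisher's exact test, adjusted p = 0.042).

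Of the clock genes 5 of 12 had a peak (Fisher's exact test, adjusted p = 0.064). These were sgg with a signal of 358.7, Pdp1 with 324.0 and CACGTG near its summit, dco with 154.6, vri with 131.3 and cry with 76.5. The core clock genes per, tim, Clk and cyc had none. Counts were 5 of 12 for glycolysis, 5 of 13 for the ER stress response, 5 of 19 for heat shock and chaperones, 4 of 14 for mitochondrial and redox stress and 4 of 18 for purine and pyrimidine synthesis. For growth signalling, with 1 symbol of 20 unmatched, the count was 2 of 19. Cell cycle and replication genes had 6 of 25. Among tissue and patterning lists, counts were 5 of 20 for muscle, 3 of 20 for neuronal differentiation, 2 of 28 for segmentation and axis genes and 1 of 8 for Hox genes. The adjusted p of each of these lists lay at or above 0.064 by Fisher's exact test. Some passed under other settings, by Fisher's exact test with adjusted p = 0.040 for clock and for glycolysis at 500 bp from a TSS, 0.011 for glycolysis with the stronger IDR peaks and 0.024 for the ER stress response with replicate 3 alone (6 of 13). Among lists meant as controls, chemoreceptor genes had 0 of 179 (Fisher's exact test, adjusted p = 2.3e-12) and eggshell and yolk genes 0 of 14 (0.26). Replication-dependent histone genes had 0 of 111 (Fisher's exact test, adjusted p = 9.0e-08), and they lie in a repeated cluster, for which the handling of reads is not stated. Of tRNA genes 11 of 295 had a peak (3.73% against 13.4% of all other genes; Fisher's exact test, adjusted p = 2.4e-07). In all, 2131 of 13968 protein-coding genes (15.3%) had an IDR summit within 1 kb of a TSS.

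Across the genome, Usf-GFP peaks lay close to promoters and almost never in coding sequence. Of the 2767 IDR summits, 1782 (64.4%, 95% interval 62.6–66.2) lay within 1 kb of a TSS. Random placements gave 23.7% on average and at most 26.2% (permutation p = 0.001, the smallest that 1000 placements allow). The median distance to a TSS was 401 bp. The lowest-signal relaxed peaks, as many in number, had 27.8% within 1 kb. Coding exons held 9 IDR summits (0.325%), where random placements gave 17.1%, and 3′ UTRs held 1.05% against 4.97%. In 5′ UTRs the share was 6.83% against 3.10%, in intergenic sequence 43.3% against 30.3%, and in introns 45.4% against 42.8%, which lay within the range of 100 placements (39.5–45.7%).

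The E-box CACGTG was rare at the summits and not more frequent there than beside them. It lay within 100 bp of 68 of 2767 summits (2.46%, 95% interval 1.94–3.10), and in 3.04% of control windows 500 bp away (exact McNemar test, p = 0.21). Of the lowest-signal relaxed peaks 3.18% had it (Fisher's exact test, p = 0.12). In 101 bp the shares were 1.01% at summits and 1.55% beside them, and the tests differed. The exact McNemar test gave p = 0.26, and the exact binomial test of all hexamers, which takes the control share as fixed, an adjusted p = 0.029. The presence of CACGTG had a weak positive correlation with the signal of the IDR peaks (Spearman rho = 0.041 over peaks; permutation p = 0.033), with 3.97% in the strongest of 10 bins, 4.33% in the sixth and 1.09% in the weakest. That correlation no longer passed with other window lengths or with replicate 3 alone (rho = 0.021), and was negative with replicate 4 alone (−0.018) and in a longer pooled list (−0.0075). Among the other E-boxes of the form CANNTG, the share at summits was lower than beside them for 6 of the 9, CAGCTG and CACCTG among them. It did not pass the test for CATATG, CAAATG and CAATTG.

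**Figure D2:**
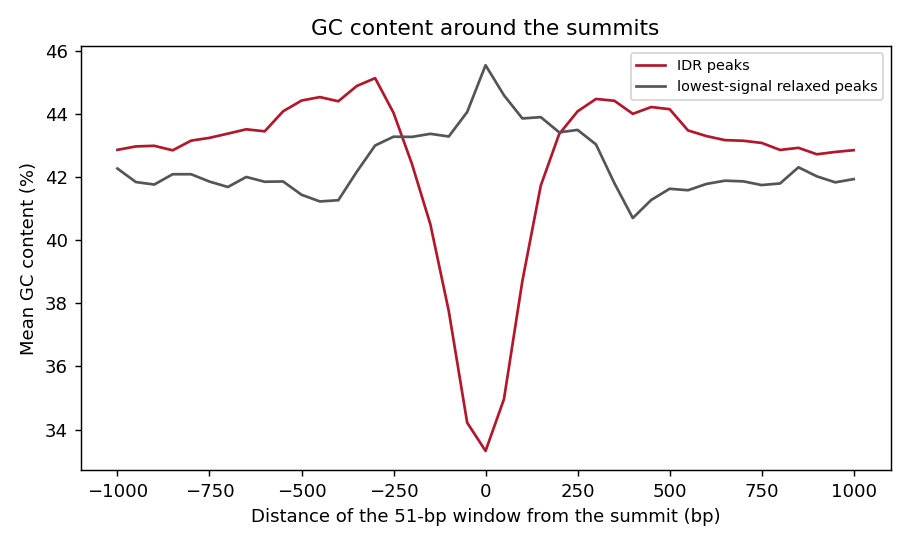
Mean GC content (percent) of 51-bp windows by distance from the summit (bp), for the 2767 IDR peaks and for as many lowest-signal relaxed peaks. At the summit the IDR peaks fell to 33.3% and the lowest-signal relaxed peaks rose to 45.5%.

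The sequence at the IDR summits was rich in A and T. In 101 bp, GC content was 33.7% ± 8.76 (SD, n = 2767 peaks) at the summit and 44.2% ± 7.76 in the control windows, and it was lower at the summit in 2226 peaks (80.4%; permutation p = 1e-05, the smallest possible). The lowest-signal relaxed peaks differed the other way, with 45.2% ± 10.1 at the summit and 41.5% ± 7.61 beside it. Of all hexamers tested, 536 were more frequent at IDR summits and 1010 less frequent. The leading ones held only A and T, such as TTAAAA at 33.5% of summits against 12.4% of control windows (exact binomial test, adjusted p = 1.9e-180).

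Against random windows matched for GC content, for lying within 1 kb of a TSS and for coding state, a control chosen after the comparisons above had given no excess, CACGTG was more frequent at the summits. The share was 2.46% against a mean of 1.75% in matched windows, a ratio of 1.41 (95% interval 1.11–1.78; permutation p = 0.0060). With windows matched also for classes of distance to a TSS, the matched share was 1.80% and the ratio 1.36 (1.08–1.72; permutation p = 0.012). The direction of this comparison thus depended on the control. With windows matched without these distance classes, 221 hexamers were more frequent at summits, 136 of them among the 536 above. The leading ones were ACAGTG (7.66% against 3.25%), CAGTGC (7.01% against 3.09%) and ACACTG (7.12% against 3.36%; each by exact binomial test, adjusted p at most 5.4e-19). CGATAG followed at 4.88% against 2.31% and GGCGCC at 1.99% against 0.540%. CACGTG in the shorter window of this test did not pass (ratio 1.39; exact binomial test, adjusted p = 0.25), nor did any other E-box.

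IDR peaks with CACGTG lay at promoters more often than those without. Of the 68, 56 lay within 1 kb of a TSS (82.4%, 95% interval 71.6–89.6), against 1726 of 2699 without the motif (63.9%; difference 18.4 points; Fisher's exact test, p = 0.0013). Among the 1383 stronger peaks the counts were 33 of 39 and 947 of 1344, which did not pass (Fisher's exact test, p = 0.072). The motif's centre lay a median of 63 bp from the summit (quartiles 25.25 and 78 bp), and within 20 bp in 15 of the 68. The search reached only 100 bp to each side of the summit, so the median lay in the outer part of that window. These distances therefore do not show a motif centred on the summit, and they were not tested against an even spread over the window.

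The replicates shared most of their strong peaks. Of the 2767 strongest peaks of replicate 3, 1972 (71.3%, 95% interval 69.6–72.9) had a summit within 100 bp among the 2767 strongest of replicate 4. Random draws from the replicate 4 list gave 8.48% on average and at most 9.83% (permutation p = 0.001, the smallest possible). Of the IDR peaks, 2615 (94.5%) were found in both relaxed lists and 0 in neither. The IDR set was itself chosen for recurrence between these replicates, so that count is no separate support. Over those 2615, the signals of the replicates correlated with Spearman rho = 0.753. On the log10 scale Pearson r was 0.818 (permutation p = 1e-05 for each, the smallest possible). Both are correlations over peaks, and what the shared control alignment adds to them was not tested.

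Among the 2767 strongest peaks, 290 of replicate 3 and 293 of replicate 4 had no summit of the other relaxed list within 100 bp. The strongest of these lay at Fer2LCH, CG3961 and MFS18 in replicate 3, with signals of 370.7, 176.2 and 170.7, and at lncRNA:CR44619, Fer2LCH and HmgZ in replicate 4, with 332.3, 317.5 and 300.2. Fer2LCH encodes the light chain of secreted ferritin. Each of the 6 had a summit of the other replicate between 101 and 199 bp away. At 500 bp, a distance chosen for this comparison after seeing the data, 29 and 38 peaks remained unmatched (1.05% and 1.37%).

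The X chromosome carried IDR peaks at a density close to that of the autosomes. It had 521 IDR peaks (22.1 per Mb), and the 4 long autosome arms 2235 (20.5 per Mb), a ratio of 1.08 (95% interval 0.979–1.19; exact binomial test, p = 0.12). Chromosome 4 had 11 (8.16 per Mb), and Y had 0. In the pooled list below the IDR set, X had fewer peaks per Mb than the autosomes, with a ratio of 0.784 (0.752–0.817; exact binomial test, p = 6.2e-33). The shares on X differed between the IDR peaks (18.9%) and the weaker peaks (14.5%; Fisher's exact test, p = 3.8e-09). That comparison with weaker peaks was chosen after seeing the data.

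**Figure D3:**
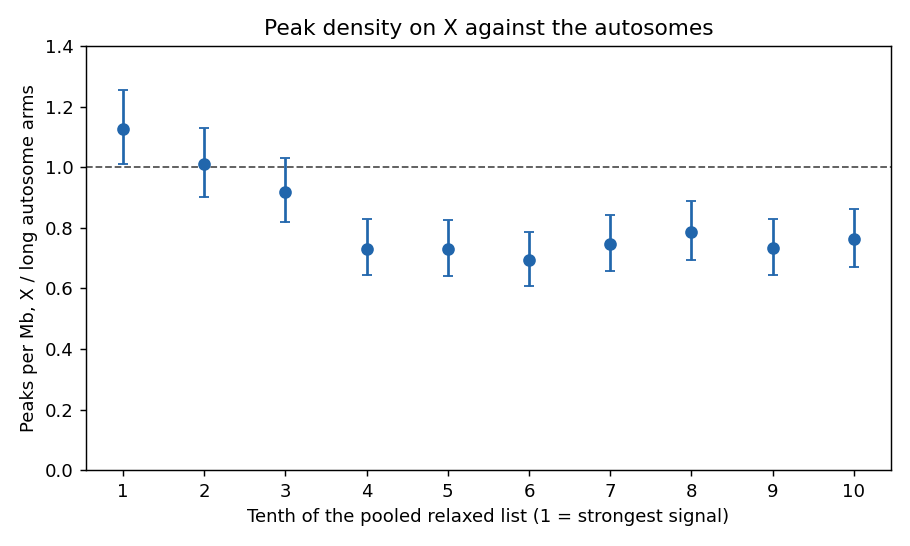
Ratio of peaks per Mb on X to the long autosome arms, with exact 95% intervals, in 10 bins of the pooled list by falling signal. The ratio was 1.13 in the strongest bin (exact binomial test, p = 0.029) and between 0.693 and 0.786 from the fourth bin on.

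On dm3 the IDR set held 2619 peaks, 148 fewer than on dm6, a difference of 5.65% of the dm3 number. On the chromosome arms alone the difference was 150. The share of IDR peaks on X among the 5 long arms was 18.9% on dm6 and 19.1% on dm3.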

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

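The counts given here were chosen after the lists had been seen. The relaxed dm3 lists held peaks on sequences outside the chromosome arms, which entered no comparison of genes or arms. There were 309 such peaks in the pooled list (1.63%), 425 in the replicate 3 list (1.72%) and 658 in the replicate 4 list (2.48%). Most lay on heterochromatic scaffolds, 285, 396 and 599 in the same order. Their median signals of 27.7, 16.3 and 14.4 were under the medians of 31.1, 18.0 and 15.6 of the whole lists. Only 2 such peaks were in the dm3 IDR set. Reads shared between repeats were not analysed here, and no control library was analysed to set these counts against.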

How the results depend on the processing

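The windows matched for GC content, the list without Rrp1, the X density of relaxed peaks and the 500 bp distance for replicate-specific peaks were chosen after seeing the data. All settings run for replicate overlap, signal correlation and promoter proximity kept their direction and side of the threshold. The X density did so near TSSs, in the stronger peaks and in single replicates, passed in the strongest of 10 bins of the pooled list (1.13; exact binomial test, p = 0.029), and reversed in all pooled relaxed peaks (0.821) and in those below the IDR set (0.784). Replicate overlap ranged from 56.4% to 79.7% over its settings. The share of IDR peaks with CACGTG stayed at 2.46% by definition against matched windows, but the control fell to 1.75%, or 1.80% with distance to a TSS matched too, and the direction reversed; it also reversed for the 1383 stronger peaks (2.82% against 2.78% beside them) and ranged from 2.60% to 2.89% in single replicates, where replicate 4 alone was reversed. The trend of CACGTG with signal was weaker at 50 bp (rho = 0.033) and 200 bp (0.032) to each side, reversed in the longer pooled list (−0.0075) and ranged from −0.018 to 0.021 in single replicates. The excess of promoters among CACGTG peaks was 14.2 points in the stronger peaks and no longer passed (Fisher's exact test, p = 0.072). The 5 higher gene lists became 2 with a background of genes with a relaxed peak, 3 with the stronger peaks (2 of the 5, and glycolysis) and 1, cytosolic ribosomal proteins, with CACGTG peaks alone. Fewer genes or peaks entered those tests. At 500 bp the count was 6, with 4 of the 5, and without Rrp1 it was 5. The 536 hexamers became 221 with matched windows. For the other changes the cause was not tested. Replicate-specific peaks fell to 1.05% and 1.37% at 500 bp. No paired analysis was possible because the samples form 1 group. Read depth, unknown here, limits which weak peaks could be called.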

Other observations

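The divergent promoters, the octamers, the windows matched for GC content, and the tests on the strongest 276 peaks and on pooled lists of other complexes were chosen only after related results were seen. Peaks at divergent promoters were frequent. Of the IDR peaks within 1 kb of a coding TSS, 672 of 1663 (40.4%) had a divergent pair of coding TSSs in that range. The share was 16.1% among the lowest-signal relaxed peaks near a coding TSS (Fisher's exact test, p = 4.8e-31) and 13.4% at random positions near one. Among the strongest 276 IDR peaks it was 94 of 208 (45.2%). Neither the relaxed peaks nor the random positions were matched to the IDR peaks for distance to a TSS or side of it.

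Longer sequences were counted at the summits against windows matched for GC content, for lying within 1 kb of a TSS and for coding state. Distance to a TSS inside that range was not matched. These counts therefore do not separate sequences particular to the peaks from sequences common close to any TSS. Of all 32896 octamers, with reverse complements merged, 175 were more frequent at the summits. The leading one, CACTGTGC, lay at 44 summits against a mean of 7.05 matched windows (exact binomial test, adjusted p = 2.1e-16), and CAGCCCTG at 30 against 3.15 (adjusted p = 2.3e-15 by the same exact binomial test). TATCGATA, the DNA replication-related element of many constitutive promoters, lay at 42 against 15.5 (exact binomial test, adjusted p = 1.9e-05). GGTCACAC lay at 26 against 7.50 (exact binomial test, adjusted p = 8.4e-05). Among the 70 CACGTG sites at IDR summits, the form TCACGTGA made up 7 (10.0%, 95% interval 4.93–19.2), against 4.01% of 16428 sites on the arms, which did not pass after adjustment over 4 symmetric forms (Fisher's exact test, adjusted p = 0.090).

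The low share of summits with CACGTG may come in part from their base composition. That share was not shown to be lower than beside the summits (exact McNemar test, p = 0.21). Windows matched for GC content held CACGTG at 1.75%, under the 3.04% beside the summits, which goes with that explanation. Composition alone would give summits and matched windows an equal share. The ratio of 1.41 between them (95% interval 1.11–1.78) lay above that. The excess over matched windows may not be specific to CACGTG, but it was not general to hexamers with as many G and C bases. In a separate draw of 20 matched windows per peak, the 492 such hexamers had a median ratio of 1.00. The ratio of CACGTG, 1.38, lay at their 92.1 percentile and under their 95th percentile of 1.45. A higher ratio was found for 38 of them. Dilution by weak peaks stays open, because the strongest 276 peaks had a share of 3.99% against 2.17% beside them (Fisher's exact test, p = 0.18). Unlike the McNemar test, that test took the 552 control windows as independent and left out their pairing with the peaks. Its p-value is therefore approximate. No biological explanation was tested, since the samples form 1 group with no library lacking the fusion protein.

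V-ATPase and cytosolic ribosomal protein genes had peaks at 70.1% (95% interval 60.8–77.9), and proteasome, respiratory chain and mitochondrial ribosomal protein genes together at 15.5% (11.1–21.3). Those other lists were picked after their shares were seen, and ribosome biogenesis (35.7%) and glycolysis (41.7%) were left out, so a general presence of peaks at constitutive promoters stays open. The V-ATPase list was written gene by gene, while the proteasome, respiratory chain and both ribosomal protein lists took every symbol of a pattern. Promoter base composition and crowded TSSs did not remove the difference in shares. The common odds ratio was 13.5 (8.87–20.4) without strata, 12.4 (8.15–18.9) within 10 strata of GC content and 9.44 (6.03–14.8) within strata of the number of TSSs. Expression in these embryos was not analysed here, so selective occupancy by Usf-GFP stays open as a hypothesis, beside a signal at highly active promoters that any antibody would give.

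The shortage of weak peaks on X was not explained by fewer annotated TSSs, since the ratio per TSS was 0.819 (95% interval 0.763–0.879) for weak pooled peaks near a TSS. It was seen in both replicates, with ratios of 0.770 and 0.777 below their strongest 2767 peaks, so 1 replicate alone could not give it. A lower number of X copies in embryos of mixed sex might lower weak signal there, and was not tested, since no control library was analysed here.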
